A study of Brassica rapa with 36 samples.

How the data were processed

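RNA was measured in Brassica rapa, in the line K2, described in the series as inducible to androgenesis (embryo formation from microspores, the immature pollen cells), and in 49CX, described as non-inducible. There were 36 libraries in 12 groups of 3. K2 was sampled as leaf, late unicellular microspores, microspores with and without heat shock, pollen, and 2-, 4- and 8-cell embryos; 49CX as leaf and the same 3 kinds of microspores. Libraries were strand-specific and made from isolated cells by a low-input protocol, per the labels' protocols. The labels give neither the length or temperature of the heat shock nor the number of cells per library.

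The deposited values are raw read counts per gene ID, with no normalization, 1 table per library. Trim Galore, HISAT2, Picard and HTSeq are named in the submitters' processing notes. Their versions and order, the strand setting of the counting, the genome build and the annotation are not given in the sources used here. Each table held the same 47135 gene IDs. Of these, 0 matched the RefSeq gene table for assembly CAAS_Brap_v3.01, and the files do not pair IDs with names. The gene lists fixed beforehand (heat shock proteins, hormone pathways, chromatin and others) were therefore not used.

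The summary entries that name no gene were left out of library sizes and tests. Reads in no annotated gene made up 53.4% to 85.3% of the reads assigned to a gene, to no gene or to several, over the 34 libraries with gene counts. K2 pollen replicates 2 and 3 held 0 counts for every gene and were left out of all tests, which leaves 1 pollen library. Gene counts in the 34 libraries ranged from 6021 to 1179935, with a median of 188617. At that range a floor of 3 counts corresponds to between 498 and 2.54 CPM (counts scaled to a common total per library). Shares of counts in single libraries are given with exact Clopper-Pearson 95% intervals. Intervals and floors cover counting error only, since reads without molecular identifiers are not independent molecules.

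Replicates were compared before use with a chi-square test over genes with a joint count of at least 20. K2 late microspore replicates 2 and 3 were the closest pair, with a chi-square per degree of freedom of 1.04 over 5483 genes (p = 0.0216 across genes). Their shares of reads outside genes were 83.5% and 77.1%, so they were kept as separate libraries. Embryo replicates were the least alike, by Pearson r of log2 CPM over the same genes. For 2-cell replicates 1 and 2 r was -0.0256, with a chi-square per degree of freedom of 16.1. For 8-cell replicate 3 r was -0.168 and -0.00789 with replicates 1 and 2. The 4-cell pairs had 0.0518, -0.139 and -0.132, over 125, 157 and 279 genes. The other embryo pairs had 0.373 to 0.404, and microspore pairs 0.721 to 0.910. Nothing in the labels says that replicates came from separate plants, so p-values measure only the spread between these samples, which may be technical.

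Genes were tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3, robust fit) on the deposited counts, with TMM factors, the filterByExpr filter on groups and Benjamini-Hochberg adjustment. A gene was called at an adjusted p under 0.05. The 18 microspore libraries formed 1 fit (9376 genes), the K2 late and heated microspores, pollen and embryos another (13023 genes), and the 6 leaf libraries the last (11786 genes). In the fit with embryos the lone pollen library is assumed to vary like the other groups, and it lowers the number of libraries the filter asks for. The difference of heat effects between lines was tested as an interaction term.

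Tissue programme sets were built from K2 pollen, leaf and embryo libraries, with no microspore library. A member had an adjusted p under 0.05 and at least 4-fold higher expression in its tissue than in each of the others, with at most 500 members kept. This gave 500 pollen, 500 leaf and 209 embryo IDs. Because 1 pollen library defines the pollen set, it has no replicate check. The low-count filter of the microspore fit left 366 pollen, 173 leaf and 82 embryo IDs to test. A member expressed in 1 microspore group alone could pass through that group. This tilts the counts of raised and lowered members, their medians and the set tests towards that group. Shares of counts use all members. The sets were tested in the 10 microspore comparisons, 30 tests in all, with limma's camera (limma 3.58.1, preset correlation 0.01, and with an estimated correlation) on log2 CPM computed with a prior count of 2, and with fry. Overlaps of called genes used Fisher's exact test across genes, which are not independent replicates. Single values per library were compared by exact 2-sided permutation tests (scipy 1.17.1), which cannot go below p = 0.1 with 3 against 3.

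The rule for IDs took, per comparison, the 2 raised most and the 2 lowered most among called genes with a mean log2 CPM of at least 3 and no overlap between groups. Since the IDs carry no names, those of the K2 heat comparison alone are printed. Folds against a group with 0 counts are lower bounds, taken as the other group's mean over 3 counts summed over the group. They do not cover the spread between replicates of the other group.

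The tests, the rule for IDs and most alternatives to these choices were written before the data were examined. These alternatives were DESeq2's size factors, library size alone, no filter on low counts, DESeq2's Wald test (DESeq2 1.42.0), limma voom with quality weights, only the groups compared, the replicate number as a block, other set sizes and folds, and leaving out each library in turn. Chosen after seeing the data were a low-count filter without pollen, leaving out both shallowest embryo libraries, summing K2 late microspore replicates 2 and 3, and thinning microspore libraries to 85651 counts each.

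The tests were checked on simulated data, with 200 genes changed by known amounts. In the simulated K2 heat comparison (8441 genes), 20 of 67 genes changed by 1 on the log2 scale, 49 of 67 changed by 2 and 61 of 66 changed by 3 were recovered, and 5 of 135 calls were false. In the simulated 49CX heat comparison (8589 genes) the same sizes gave 8 of 67, 40 of 67 and 47 of 66, with 8 of 103 calls false. In the simulated difference of heat effects (7929 genes), 5 of 67, 35 of 67 and 48 of 66 were recovered, with 8 of 96 calls false. In the simulated leaf comparison (10975 genes) 8 of 67, 58 of 67 and 54 of 66 were recovered, with 5 of 125 calls false.

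The embryo comparisons did not hold the 5% rate in simulation when each gene kept its own dispersion. Unchanged genes made up 36 of 66 calls for 2-cell embryos against heated microspores (11466 genes) and 23 of 55 for 8-cell embryos against late microspores (11458 genes). They made up 6 of 7 calls for 4-cell against 2-cell (11097 genes) and 15 of 40 for 8-cell against 4-cell embryos (11090 genes). With a single dispersion for all genes there were 0 false calls among 20, 15, 2 and 6 calls in these 4 comparisons; the cause of the excess was not tested. The share of false calls depends on how many genes change, here 200, so it does not give the share in the real data. Calls in embryos are reported with this limit.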

Results

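The series follows transcript levels along androgenesis in Brassica rapa, in a line that can be induced (K2) and a line that cannot (49CX). It holds 36 libraries, 3 for each of 12 groups, of which 34 had gene counts. Microspore libraries held 85651 to 529458 gene counts, and embryo libraries 6021 to 170479. K2 leaf held 959801 ± 210190 and 49CX leaf 425101 ± 183542 (SD, n = 3), and the single usable pollen library 118317. Both shallowest libraries were embryos, with 6021 counts in 2-cell replicate 3 and 8549 in 4-cell replicate 1.

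Expression was summarised by 3 sets of gene IDs that mark pollen, embryo and leaf, derived from K2 libraries other than microspores. The pollen set held 45.3% of gene counts in pollen (45.05% to 45.62%, exact Clopper-Pearson 95% interval) and 0.459% ± 0.0841 in K2 leaf. The embryo set held 5.89% ± 0.663 in 2-cell, 5.78% ± 0.730 in 4-cell and 7.21% ± 0.873 in 8-cell embryos. The leaf set held 14.7% ± 1.45 in K2 leaf and 17.0% ± 1.78 in 49CX leaf (SD, n = 3 except pollen). These libraries, apart from 49CX leaf, defined the sets, so the values describe the sets and test nothing.

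**Figure D1:**
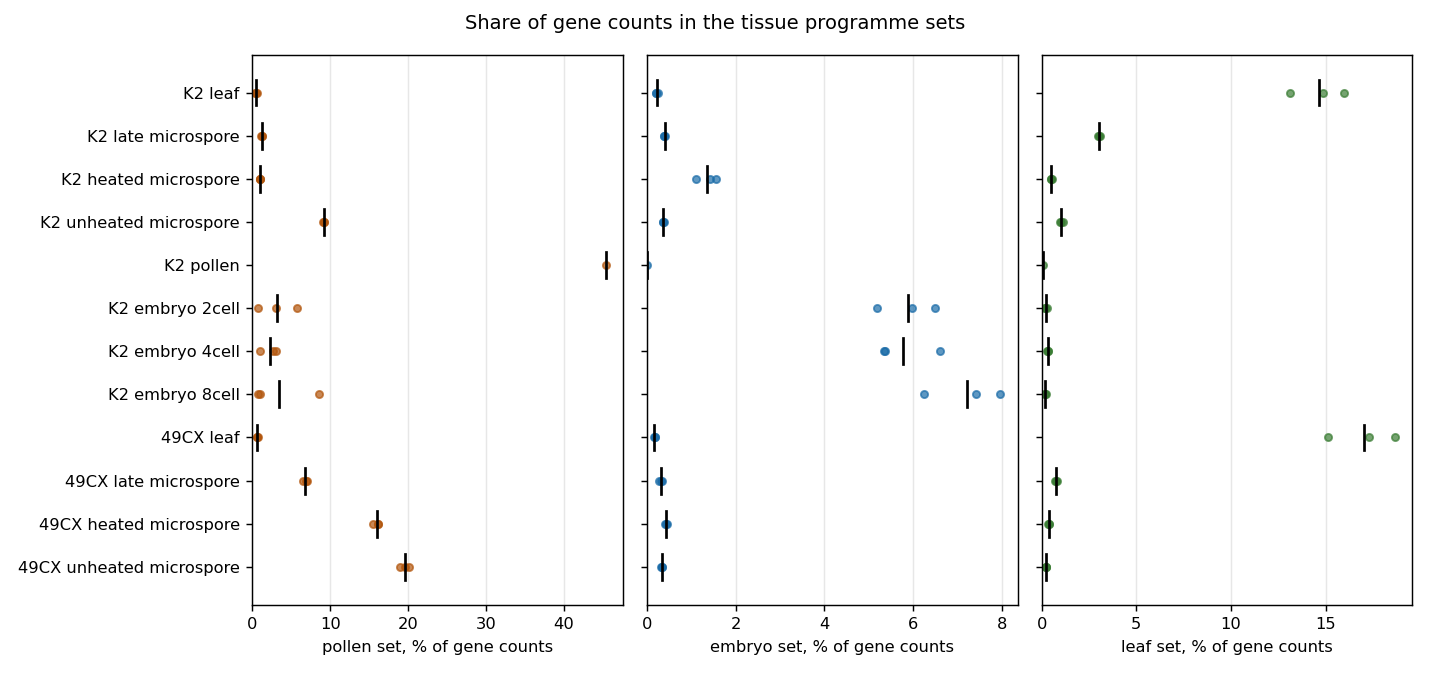
Share of gene counts (percent, x axis) in the pollen, embryo and leaf sets for each library (points) and group mean (bars), by group. In microspores the pollen set runs from 1.0% in heated K2 to 19.5% in unheated 49CX, and the embryo set is highest in heated K2, at 1.36%.

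The first comparison asks what heat shock changed in K2. Pollen set genes were lower in heated than in unheated microspores: they held 1.0% ± 0.00762 of gene counts with heat and 9.16% ± 0.0912 without (SD, n = 3). Embryo set genes were higher, at 1.36% ± 0.236 against 0.371% ± 0.0195, and leaf set genes lower, at 0.508% ± 0.0255 against 1.04% ± 0.0885. Of 366 pollen set genes tested, 200 fell and 29 rose, with a median log2 change of -1.64. Of the 82 embryo set genes, among 209, that passed the low-count filter, 62 rose and 7 fell, with a median of 2.54. A member could pass through heated K2 alone, which tilts these values towards a rise. The shares of counts above use all members. Of 173 leaf set genes, 95 fell and 9 rose, with a median of -1.56. Across the 500 leaf set members, levels followed those of K2 leaf with a Spearman rho of 0.484 in unheated and 0.180 in heated K2; genes are not independent replicates. The sets moved against the other genes in camera (adjusted p = 1.35e-11 for pollen, 4.28e-13 for embryo and 7.46e-07 for leaf), and each call held with an estimated correlation (adjusted p = 0.00103, 0.000435 and 0.00567).

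Across all genes, 5290 of 9376 were called in K2, 2590 higher and 2700 lower with heat (edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted). Of these, 2266 rose and 2340 fell by at least 2-fold. Scaling by library size alone gave 3435 higher and 2125 lower, since it moves the median of all genes by 0.36 (log2). CPM did not overlap between the groups for 57.0% of genes, where chance gives 10%.

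The IDs lowered most were BraC09g040050.1 and BraC04g009110.1, and those raised most BraC07g040390.1 and BraC04g012970.1. BraC09g040050.1, a pollen set member, had 7727 ± 425 TMM-scaled CPM without heat and 0 counts with heat, at least 1993-fold lower. BraC04g009110.1 had 1782 ± 135 CPM without heat and 0 counts with it, at least 459.6-fold lower. BraC07g040390.1 had 491 ± 306 CPM with heat (177 to 788) and 0 counts without, at least 107-fold higher for the mean. BraC04g012970.1 had 430 ± 137 CPM with heat and 0 counts without, at least 93.9-fold higher (SD, n = 3). Their adjusted p-values (edgeR) were 3.11e-122, 8.2e-83, 2.77e-09 and 1.52e-36. In K2 late microspores, by library size, BraC04g012970.1 already had 145 ± 41.7 CPM and BraC07g040390.1 a total of 1 count, while BraC09g040050.1 had 515 ± 36.8 and BraC04g009110.1 265 ± 90.3 CPM (SD, n = 3). Both lowered IDs were lower in pollen than in unheated K2 on this scale. BraC09g040050.1 had 549 CPM in the single pollen library and 5692 ± 346 in unheated K2. BraC04g009110.1 had 42.3 and 1313 ± 105. On the same scale BraC04g012970.1 stood at 6464 ± 3592 in 2-cell, 4405 ± 2077 in 4-cell and 3735 ± 2217 in 8-cell embryos. BraC07g040390.1 stood at 10228 ± 6520 in 2-cell, 179 ± 189 in 4-cell and 1152 ± 991 in 8-cell embryos (SD, n = 3).

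The same comparison was made in 49CX. The pollen set stayed high, at 15.9% ± 0.354 of gene counts with heat and 19.5% ± 0.604 without (SD, n = 3). Of its 366 genes 62 fell and 10 rose, with a median of -0.32. The embryo set held 0.427% ± 0.0183 with heat and 0.332% ± 0.0207 without, with 7 of 82 genes higher, 3 lower and a median of 0.98. Both calls held with an estimated correlation (camera, adjusted p = 0.0253 for pollen and 0.0281 for embryo). The leaf set held 0.376% ± 0.0270 with heat and 0.243% ± 0.00491 without, with 2 of 173 genes higher and 0 lower. Its camera call (adjusted p = 0.00789) was lost with an estimated correlation (adjusted p = 0.0971), while fry called the set higher (adjusted p = 0.0159). The ID with 0 counts in heated K2, BraC09g040050.1, had 8286 ± 1175 CPM with heat and 12061 ± 1596 without in 49CX.

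In 49CX 874 of 9376 genes were called by edgeR, 350 higher and 524 lower with heat, and 2043 had an unadjusted p under 0.05. The direction turned by library size alone, with 549 higher and 228 lower, and not with DESeq2's size factors, with 353 and 505. It also turned when only the 6 libraries compared were fitted, with 331 higher and 262 lower, where the filter left fewer genes. DESeq2's Wald test called 510 genes and a fit with no filter on low counts 574. With all microspore libraries thinned to 85651 counts, 300 genes were called in 49CX and 1844 in K2.

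The difference between the heat effects of the lines was tested directly. Relative to 49CX, the K2 heat effect was lower for pollen set genes by a median of 1.35 on the log2 scale (median difference -1.35) and for leaf set genes (-2.08), and higher for embryo set genes (1.57). The interaction was called for 149 lower and 18 higher of 366 pollen set genes, for 47 lower and 1 higher of 173 leaf set genes, and for 18 higher and 5 lower of 82 embryo set genes. Each held with an estimated correlation (camera, adjusted p = 0.00244 for pollen, 0.00182 for leaf and 0.00103 for embryo). The leaf set's Spearman rho with K2 leaf, 0.484 and 0.180 in unheated and heated K2, was 0.123 and 0.157 in 49CX. In all, 2357 of 9376 genes differed in edgeR, 836 with a higher and 1521 with a lower effect in K2.

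Across 9376 genes the log2 heat effects of the lines had a Pearson r of 0.325 and a Spearman rho of 0.393; genes are not independent replicates. Of 670 genes called in both lines, 607 changed in the same direction. They were 178 raised in both, where independent lists give 96.7, and 429 lowered in both, where they give 150.9. The median absolute log2 change was 1.08 in K2 and 0.55 in 49CX.

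**Figure D2:**
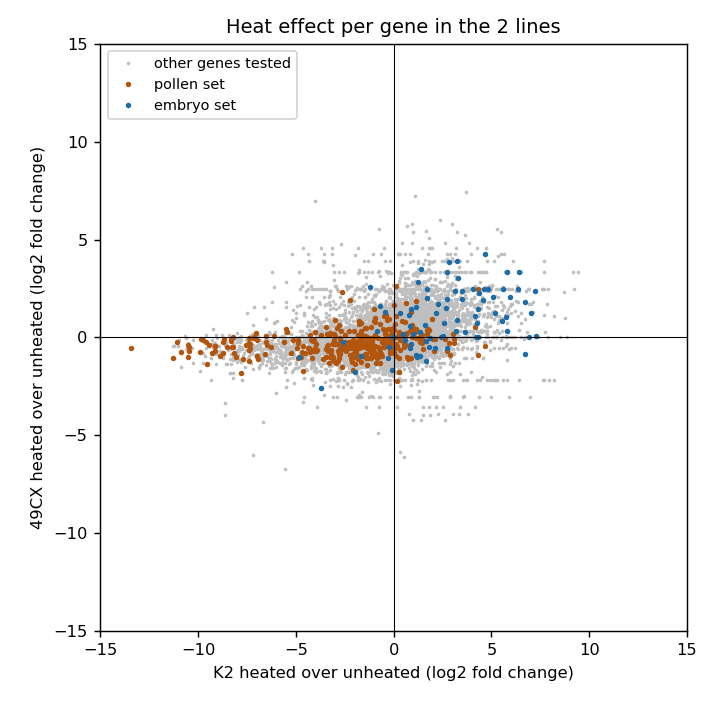
Log2 fold change of heated over unheated microspores in K2 (x axis) and 49CX (y axis) for the 9376 genes tested, with pollen and embryo set members coloured. Pollen set genes spread to the left, with a median of -1.64 in K2 and -0.32 in 49CX.

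Late unicellular microspores are the stage before heat. In K2 the pollen set rose from 1.20% ± 0.0338 in late microspores to 9.16% ± 0.0912 without heat, with 211 of 366 genes higher and 15 lower. With heat its share was 1.0% ± 0.00762, with 57 genes higher and 72 lower. Camera did not call the set (adjusted p = 0.961), while fry called it lower (adjusted p = 0.0133). In 49CX the pollen set rose from 6.79% ± 0.288 in late microspores both without heat, to 19.5% ± 0.604 with 290 genes higher and 3 lower, and with heat, to 15.9% ± 0.354 with 256 higher and 5 lower (SD, n = 3). These 3 rises held with an estimated correlation (camera, adjusted p = 0.000125, 4.13e-06 and 4.13e-06).

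The embryo set rose between late and heated microspores in K2, with 62 of 82 genes higher and 5 lower (camera, adjusted p = 0.000125 with an estimated correlation). The low-count filter tilts this count too. In 49CX 15 of the 82 rose and 2 fell. That camera call (adjusted p = 0.0336) was lost with an estimated correlation (adjusted p = 0.168) and without 49CX late replicate 1 or 49CX heated replicate 3. Fry called the set higher (adjusted p = 0.000326). Leaf set genes fell from 3.04% ± 0.0719 in K2 late microspores to 0.508% ± 0.0255 with heat, 158 of 173 lower and 3 higher, and to 1.04% ± 0.0885 without heat, 132 lower and 3 higher. In 49CX the leaf set fell as well, with 25 lower and 1 higher with heat, and 43 lower and 1 higher without (camera, adjusted p = 0.00521 and 0.0014 with an estimated correlation).

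Against late microspores, edgeR called 4119 genes in heated K2 (1916 higher, 2203 lower) and 4285 in unheated K2 (2143 higher, 2142 lower). In 49CX it called 1925 with heat (1213 higher, 712 lower) and 2552 without (1545 higher, 1007 lower). By library size alone the splits were 2224 higher and 1923 lower for heated K2, 1770 and 2738 for unheated K2, 935 and 1361 for heated 49CX, and 980 and 2663 for unheated 49CX. With only the groups compared, heated 49CX gave 1195 calls and unheated 49CX 1615. Fewer genes passed the low-count filter in these fits, and a larger share of them was called.

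The breadth of expression moved with these groups. The 50 most abundant genes held 11.9% ± 0.154 of counts in unheated and 4.68% ± 0.526 in heated K2, and 19.5% ± 0.655 in unheated and 15.7% ± 0.164 in heated 49CX. At a common depth of 5000 counts, 3827 ± 45.4 genes were detected in heated and 3333 ± 40.7 in unheated K2, and 3232 ± 20.6 and 2867 ± 52.6 in 49CX (SD, n = 3). In every one of these comparisons the groups did not overlap, with an exact permutation p = 0.1, the smallest that 3 against 3 allows. Reads in no annotated gene made up 79.9% ± 0.151 in unheated and 63.4% ± 0.993 in heated K2. In 49CX they made up 65.7% ± 5.80 without heat and 70.4% ± 0.597 with heat, with overlapping ranges (SD, n = 3, not tested).

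The lines already differed before heat. In late microspores the pollen set was lower in K2, with 168 of 366 genes lower and 4 higher, and the leaf set higher, with 142 of 173 genes higher and 2 lower. Leaf set genes held 3.04% ± 0.0719 of counts in K2 and 0.745% ± 0.0587 in 49CX (SD, n = 3). Without heat the pollen set was lower in K2 for 294 genes and higher for 6, and with heat lower for 324 and higher for 4. The leaf set was higher in K2 without heat for 106 genes and lower for 3, and with heat 24 were higher and 13 lower. With heat camera did not call the set (adjusted p = 0.199, and 0.412 with an estimated correlation). Fry called it higher in K2 (adjusted p = 0.0312). Embryo set genes differed with heat, 51 of 82 higher in K2 and 7 lower (camera, adjusted p = 0.00214 with an estimated correlation). This count is tilted too, since a member could pass the low-count filter through heated K2 alone. In late microspores 12 embryo set genes were higher and 12 lower (camera, adjusted p = 0.961 with the preset correlation). The pollen and leaf set calls in late microspores held with an estimated correlation (adjusted p = 0.000203 and 6.71e-06).

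Between lines, edgeR called 3033 genes in late microspores (1550 higher in K2, 1483 lower), 3057 without heat (1443 higher, 1614 lower) and 4676 with heat (2348 higher, 2328 lower). Leaves differed in 5225 of 11786 genes, 2778 higher in K2 and 2447 lower. Reads in no annotated gene made up 55.2% ± 2.09 in K2 leaf and 74.9% ± 10.6 in 49CX leaf, with no overlap (SD, n = 3, not tested). By library size alone the splits were 1429 and 1629 in late microspores (2075 and 1173 with no filter on low counts), 2267 and 1203 without heat, 3371 and 1896 with heat, and 3552 and 1842 in leaf.

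**Figure D3:**
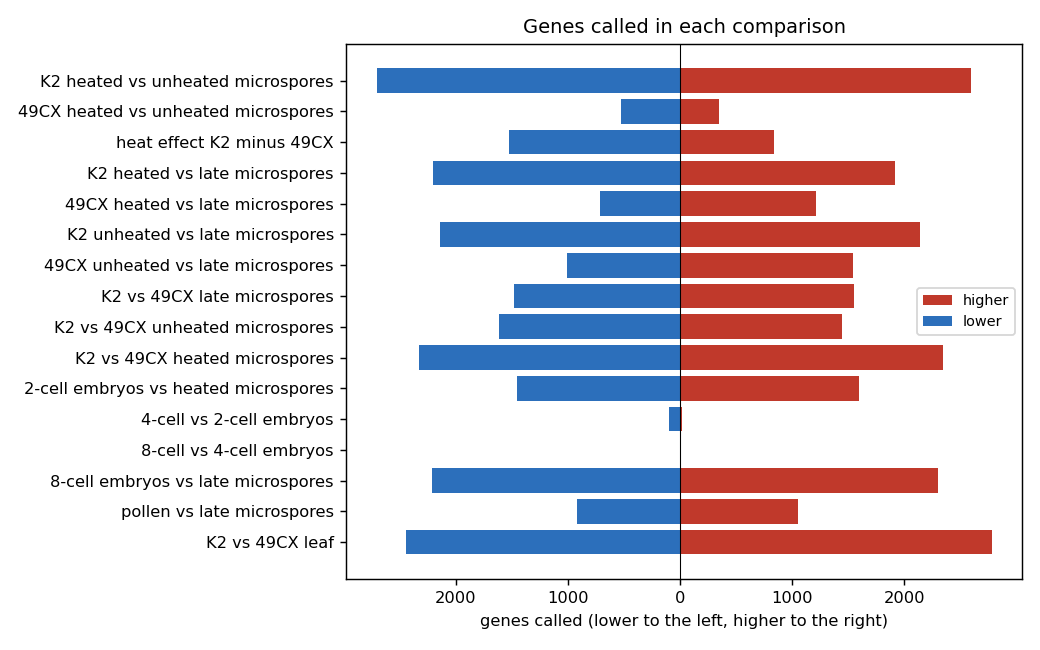
Number of genes called by edgeR in each comparison, higher to the right and lower to the left (x axis). K2 heat changed 5290 genes and 49CX heat 874; the 4-cell against 2-cell and 8-cell against 4-cell embryo bars hold 114 and 2.

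Embryos were compared with microspores and with each other in K2. Genes of 8-cell embryos against late microspores numbered 4513 of 13023, 2300 higher and 2213 lower in embryos. Genes of 2-cell embryos against heated microspores numbered 3050, 1598 higher and 1452 lower. Of these, 493 higher and 1438 lower had no overlap in CPM between groups and a mean log2 CPM of at least 3. Among all genes tested 33.3% had no overlap. With only the groups compared, 2582 genes were called for 8-cell embryos against late microspores and 1743 for 2-cell embryos against heated microspores. Fewer genes passed the low-count filter in these fits, and a larger share of them was called, so the counts are not directly comparable. In the fit with all groups the 2-cell count fell to 1773 without heated replicate 1 and 1911 without heated replicate 2. By library size alone the 2-cell split was 1497 higher and 2504 lower, and without 8-cell replicate 3 the 8-cell split was 1659 and 2624. The 8-cell split also turned with DESeq2's size factors (2271 and 3017) and by library size alone (2322 and 2752).

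Embryo libraries were uneven in pollen set genes, which held 3.15% ± 2.54 of counts in 2-cell, 2.22% ± 1.08 in 4-cell and 3.41% ± 4.49 in 8-cell embryos (SD, n = 3). The highest were 5.74% in 2-cell replicate 2 and 8.59% in 8-cell replicate 3. Across genes, replicates of an embryo stage were not alike either, with a Pearson r of log2 CPM between -0.168 and 0.404. Without 2-cell replicate 2 there were 2169 calls for 2-cell embryos against heated microspores, and without 8-cell replicate 3 there were 4283 for 8-cell embryos against late microspores. In simulated data of these 2 comparisons, with 200 genes changed, 36 of 66 and 23 of 55 calls were false. The real comparisons called 3050 and 4513 genes, so these shares do not give the share of false calls among them.

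Steps between embryo stages were not resolved. The counts were 114 genes for 4-cell against 2-cell (17 higher, 97 lower) and 2 for 8-cell against 4-cell (2 higher, 0 lower), with 2332 and 1795 at an unadjusted p under 0.05. With only the 6 libraries compared, edgeR called 0 in both. The low-count filter left far fewer genes to test there than in the main fit. These 0 calls are therefore not a like-for-like check of the 114 and 2. DESeq2's Wald test on all libraries of the fit called 120 and 1. The 4-cell direction turned with the scaling, to 83 higher and 30 lower with DESeq2's size factors and 71 and 33 by library size alone. Leaving out 1 library gave 357, 203, 37, 21 and 48 calls for 4-cell against 2-cell (without 2-cell replicates 2 and 3 and 4-cell replicates 1, 2 and 3), and 49 for 8-cell against 4-cell without 8-cell replicate 3. In simulated data of these steps most of the 200 changed genes were missed, and 6 of 7 and 15 of 40 calls were false. These shares too depend on the number of genes changed.

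Genes changed by heat in K2 were compared with those that separate 8-cell embryos from late microspores, over 7810 genes and with no shared library. These 7810 genes passed the low-count filters of both fits, and 753 were called higher and 2014 lower in 8-cell embryos. Among all 13023 genes of the embryo fit 2300 were higher and 2213 lower. The microspore filter thus removed mostly genes higher in embryos, which lowers the medians below. Of 2478 raised by heat, 372 were also higher in 8-cell embryos, where independent lists give 238.9 (Fisher's exact test across genes, odds ratio 2.30, adjusted p = 9.23e-26). Of 1968 lowered by heat, 726 were also lower in embryos, where independent lists give 507.5 (odds ratio 2.07, adjusted p = 3.13e-36). Leaf set genes, lower with heat in K2, held 3.04% ± 0.0719 of counts in late microspores and 0.192% ± 0.0248 in 8-cell embryos (SD, n = 3). Their part in this overlap was not tested. Of those raised by heat 380 were lower in embryos, where independent lists give 639.0 (odds ratio 0.410, adjusted p = 7.48e-49). As a whole the genes raised by heat in K2 were lower in 8-cell embryos than in late microspores (median log2 change -0.293, 41.7% higher). They fell less than the other genes tested (median -0.972). Genes lowered by heat in K2 had a median of -1.15 (29.4% higher), against -0.654 for the others. In 49CX 55 of 307 raised genes were higher in embryos, against 29.6, and 130 of 402 lowered genes were lower, against 103.7 (adjusted p = 7.45e-06 and 0.0037). Of those raised in 49CX 58 were lower in embryos, against 79.2 (odds ratio 0.661, adjusted p = 0.00502). Genes lowered by heat in 49CX were also in excess among those higher in embryos, 51 against 38.8 (odds ratio 1.39, adjusted p = 0.0406), while in K2 they numbered 186 against 189.7 (adjusted p = 0.757). Genes with a higher heat effect in K2 than in 49CX were in excess among those higher in embryos, 136 against 78.4, and fewer among those lower, 110 against 209.7 (odds ratio 2.08 and 0.419, adjusted p = 3.56e-11 and 1.05e-18). Genes with a lower heat effect in K2 than in 49CX were in excess both among those higher in embryos, 133 against 103.5, and among those lower, 411 against 276.7 (adjusted p = 0.00221 and 6.73e-22). Without 8-cell replicate 3 the observed over the expected overlap was 2.22 for genes raised in K2, against 1.56 with it. Whether the overlaps differ between lines was not tested.

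Pollen against late microspores rests on 1 pollen library and has no replicate check. The fit called 1966 genes, 1051 higher and 915 lower in pollen, with a median log2 change over all genes of -3.45. The split was not stable, with 1357 higher and 220 lower under DESeq2's size factors and 917 and 5287 by library size alone. It was 1215 and 2830 with only the groups compared, 544 and 907 with a filter without pollen, and 1014 and 1928 without both shallowest embryo libraries. At 5000 counts pollen showed 1376 genes, against 3664 ± 37.5 in K2 late microspores (SD, n = 3).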

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

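The tests of depth, of reads taken by abundant genes, of stage, of pollen RNA in embryos and of leaf set RNA below were chosen after the values they rest on had been seen; the test of scaling without abundant genes and the splits of the libraries were not.

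The heat effect differed between lines, by the interaction test, for 2357 genes, and for the pollen set (median difference -1.35), the leaf set (-2.08) and the embryo set (1.57). The leaf set held 0.243% ± 0.00491 of counts in unheated 49CX (SD, n = 3), which leaves little room for a fall with heat there. In 100 splits of the heat labels within each line, 3 gave as many genes as the real one, itself included. The real split gave 2210 genes in the 12 libraries compared and the highest other 2652. The 2 others kept the heat labels of K2 and changed those of 49CX, so the splits bear on the heat effect in K2 and do not exclude chance for the difference between lines.

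More genes changed by heat in K2 than in 49CX. Lower depth is argued against as the whole cause: at equal depth K2 calls were 6.15 times 49CX calls. Abundant genes are argued against too: without 669 IDs (the pollen set and each library's 50 most abundant), with the scaling computed anew, the ratio was 6.30, against 6.05 with them, and with the other genes thinned to 72876 counts in every library, so that reads taken by those IDs no longer differ, it was 5.75 (1742 and 303 calls). 49CX microspores may have been further along the pollen path before heat, since their late pollen set share was 5.67 times that of K2, but line and stage cannot be told apart with 1 line of each kind. The heat effects differed by the interaction test, and whether that difference comes from the line, the stage or a difference between libraries stays open. Reads in no annotated gene made up 79.9% ± 0.151 in unheated and 63.4% ± 0.993 in heated K2 (SD, n = 3). In 49CX they made up 65.7% ± 5.80 and 70.4% ± 0.597, with overlapping ranges. Whether these shares bear on the number of calls was not tested.

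Embryo libraries were uneven in pollen set RNA: with sets rebuilt without 2-cell replicate 2 and 8-cell replicate 3, these held 15.2% (14.98% to 15.33%) and 19.3% (19.0% to 19.5%) of counts in the pollen set, against 0.173% (0.154% to 0.194%) in 2-cell replicate 1 and 0.244% (0.209% to 0.284%) in 8-cell replicate 1, with 7.69% (7.03% to 8.39%) in 2-cell replicate 3, 5.404% (4.93% to 5.90%) in 4-cell replicate 1, 4.22% (4.01% to 4.43%) in 4-cell replicate 3, 1.02% (0.913% to 1.14%) in 4-cell replicate 2 and 0.934% (0.866% to 1.01%) in 8-cell replicate 2 between them. A mix-up with pollen libraries is argued against by the embryo set, whose lower share in them was 1.18 times the lowest of the other embryo libraries. Pollen or pollen-like cells in these samples are a candidate source: of the 100 most abundant pollen set transcripts, 100% were detected in both, at a median of 19.2% and 24.7% of their pollen level. Both were singled out for a high pollen set share, so this detection largely restates that share. Detection was 31% and 33% in 2-cell and 8-cell replicate 1, and 64% to 76% in the other embryo libraries. In 2-cell replicate 3 and 4-cell replicate 1 the median was 8.43% and 6.94% of the pollen level. The rebuilt set took IDs that were low in the remaining embryo libraries, so the lower values there are partly fixed by its construction, and the labels name no step that removes such cells. Embryos that keep part of the pollen programme would give the same values, and no biological explanation was tested.

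Leaf set RNA was higher in K2 than in 49CX late microspores. A sequence difference of 49CX from the reference is argued against, since in leaf the set's share in 49CX was 1.16 times that of K2, while in late microspores it was 0.245 times. Cells of green tissue in the K2 late samples are a candidate source: across the 500 set members levels followed those of leaf with a Spearman rho of 0.546, little over the bound of 0.5 set for the test, against 0.282 in 49CX late microspores. In unheated K2 rho was 0.484 and in heated K2 0.180, and the 100 members most abundant in leaf stood at a median of 14.3% of their leaf level in late, 4.68% in unheated and 0.887% in heated K2, against 1.67% in 49CX late microspores. Expression of these genes in the microspores themselves, and a difference in stage, stay open and untested.

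The tables of K2 pollen replicates 2 and 3 hold 4594119 and 4395263 reads in no annotated gene, and 0 in any gene. The annotation and the strand setting of the counting are not given in the sources used here, so a fault in the counting is not excluded for these tables, nor a part of that setting in the shares of 53.4% to 85.3% elsewhere.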

How the results depend on the processing

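Thinning, the filter without pollen, leaving out both shallowest embryo libraries and summing K2 late replicates were chosen after seeing the data. Over the counts of called genes, set tests, overlaps and correlation, 666 values under alternatives stayed on their side of the threshold or within 1.5 times the count, 44 counts moved further, 4 set calls were lost and no called set turned direction; the cause was not tested unless stated. For single IDs 826 values kept their call and 59 lost it. An ID that an alternative's filter removed has no value there and was not counted as lost. The IDs were also picked for their large called changes in the main fit, so these numbers overstate stability. The scalings moved the median of all genes by up to 0.88 (log2, 8-cell against 4-cell embryos), so splits of higher against lower calls are relative to the scaling. Thinning to equal depth (fewer counts and genes) gave 1844 calls for K2 heat, 300 for 49CX heat, 1052 for their difference, 1287 and 1512 for heated and unheated K2 against late, 1067 and 1222 for 49CX, and 1284, 1051 and 1887 between lines in late, unheated and heated microspores. With no filter on low counts, 49CX heat gave 574, 4-cell against 2-cell 295 and 8-cell against 4-cell 52. DESeq2's Wald test gave 510 for 49CX heat, 1 for 8-cell against 4-cell and 1250 for pollen (1177 higher, 73 lower), and DESeq2's size factors 1 for 8-cell against 4-cell. With only the groups compared, 49CX gave 1195 (heated against late) and 1615 (unheated against late), 2-cell against heated 1743, 8-cell against late 2582, pollen 4045, and both embryo steps 0. In each of these fits the low-count filter left fewer genes to test than in the main fit, so the counts are not directly comparable. Limma voom gave 1830 for 2-cell against heated and 0 for 4-cell against 2-cell, and library size alone 6204 for pollen. Without pollen in the filter the embryo steps gave 51 and 1, and without both shallowest libraries 46 and 0. With an estimated correlation camera lost the leaf set in 49CX heat (median 0.61) and the embryo set in heated against late 49CX (0.63), the latter also without 49CX late replicate 1 (0.54) or 49CX heated replicate 3 (0.21), over a range of 0.21 to 0.70. The leaf set median in 49CX heat was 0 without 49CX heated replicate 1. Leaving out each library in turn gave 4929 to 5449 for K2 heat, 583 to 693 for 49CX heat and 2080 to 2421 for their difference. It gave 1773 to 3411 for 2-cell against heated (1773 and 1911 without K2 heated replicates 1 and 2), 21 to 357 for 4-cell against 2-cell (lowest without 4-cell replicate 2, highest without 2-cell replicate 2) and 1 to 49 for 8-cell against 4-cell (highest without 8-cell replicate 3).

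Replicate numbers did not pair the libraries: the lowest correlation of same-numbered deviations was -0.0943. With the replicate number as a block, K2 heat gave 5216 calls, 49CX heat 849, their difference 2303 and 8-cell against 4-cell 7.

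For each comparison of 3 against 3 libraries there are 10 splits, too few for a share under 0.05. Fitted alone, the real split and the highest other gave 4224 and 0 for K2 heat, 593 and 0 for 49CX heat, 3650 and 0, 1195 and 0, 3457 and 0, and 1615 and 0 against late microspores (heated K2, heated 49CX, unheated K2, unheated 49CX), 2125, 2283 and 3159 with 0 between lines (late, unheated, heated), 5225 and 0 in leaf, 1743 and 0 for 2-cell against heated and 2582 and 0 for 8-cell against late; for these, 1 split gave as many, the real one. For 4-cell against 2-cell it was 0 and 14, and for 8-cell against 4-cell 0 and 1, with all 10 splits giving as many. The shallowest libraries (6021 and 8549 counts) are in the embryo steps. When these steps were fitted alone, the low-count filter left far fewer genes to test than in the main fit.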
